A study of Mus musculus with 4 samples.

How the data were processed

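Gene expression was measured in bone marrow-derived dendritic cells of C57BL/6 mice, antigen-presenting cells grown from marrow precursors in culture. Per the labels, the cells were harvested on day 7, kept for 2 h with 0.3 µM sulforaphane (an isothiocyanate from cruciferous vegetables that activates the transcription factor NRF2) dissolved in DMSO, or with DMSO alone, and then stimulated for 1 h with 100 ng/ml lipopolysaccharide (LPS), the bacterial ligand of TLR4. The sulforaphane dose is low for this compound and was not checked against another source here. Each treatment had 2 samples, so 4 arrays were used. The labels do not say whether the replicates came from separate mice or cultures. The p-values of single genes therefore measure only the spread between these samples, which may be technical. No sample without LPS was analysed here.

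Per the labels' protocols, biotin-labelled cRNA was hybridised to Affymetrix arrays. The deposited values are on a log2 scale, made with RMA in R 2.15.1 per the submitters' processing notes. RMA subtracts background, quantile-normalizes the arrays against each other and summarises the probes of each probe set. The log base is not written in the table and was read as 2 from the method and the range of the values, and so every fold given here rests on that reading. Filters and the summarization level are not given in the sources used here. The table held 41345 probe sets with no missing value. A platform annotation listed 25335 of them, of which 23521 had exactly 1 gene symbol and 1814 had several. The other 16010 were not listed and are unnamed here. Of the entries with a single symbol, 23328 were matched by Entrez identifier to RefSeq gene names of assembly GRCm38.p6, and no symbol needed updating.

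Each gene was represented by the probe set with the highest mean over the 4 arrays, and genes with a mean above the 40th percentile of all probe sets, a log2 value of 2.91, were tested. This left 14652 genes. The difference between sulforaphane and DMSO was fitted with limma 3.58.1 (lmFit and eBayes) in R 4.3.3 without a replicate block, and adjusted by the Benjamini-Hochberg method with a threshold of 0.05. The fit had 2 residual degrees of freedom per gene and 4.02 prior degrees of freedom. Errors of differences are moderated standard errors (SE) and intervals cover 95%. A difference of at least 1.5-fold in which both sulforaphane arrays lay beyond both DMSO arrays was counted separately as a description of size.

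The 32 gene lists, the tests, the settings and the rule for naming genes were fixed before the data were examined, except where a later choice is stated. Lists with at least 4 tested members were tested with camera at a preset inter-gene correlation of 0.01. Camera at an estimated correlation was run beside it. So was fry, which asks whether the genes of a list move one way on balance without comparing them with other genes. Camera compares a list with the other genes, so its p-value at the preset correlation rests on the spread over genes, not between the arrays. At an estimated correlation it has only the 2 residual degrees of freedom of the fit, so it could hardly pass after adjustment. Fisher's exact p-values, and the permutation p-value of a gene family, also compare genes with genes. Members were also tested with the p-value adjusted over the list alone. Of 736 listed names, 625 were tested, and 2 of the names were matched through a synonym (Il36g and Il36a, given in the annotation as Il1f9 and Il1f6). The naming rule took up to 12 genes per direction past the threshold whose groups did not overlap, every IL-12 family member, and up to 4 members with the smallest unadjusted p from each list described, and used rose or fell only for those past the threshold over all genes or, said so, over the list alone. A gene named by several parts of the rule counts under each. Predicted genes without a name beyond a number were passed over, as were probe sets with several symbols or none.

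The procedure was tested on simulated arrays with the means of the 14652 genes and 200 genes changed per run. Over 5 runs it called 6% of genes changed 1.5-fold, 65.2% of those changed 2-fold, 94.8% at 3-fold and 99.2% at 4-fold. Of 72260 unchanged genes in these runs 27 were called. In 5 runs without change it called 0 genes and 0 lists, and a shifted list was called in 5 of 5 runs. The noise was drawn separately for each gene, with no correlation between genes and no array effect. Every member of the shifted list was given the same shift. These runs therefore give no error rate for camera on lists whose genes move together, such as interferon-stimulated genes (estimated correlation 0.17). The alternatives were no intensity filter, a filter at the 60th percentile, median centring, a second quantile normalization, the mean of a gene's probe sets, every probe set on its own, a replicate block, each array left out in turn, an intensity trend or robust estimation in eBayes, and the list tests above. A threshold of 0.10 was added after seeing the data. The number of arrays limits the precision. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.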

Results

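Expression was compared between 2 arrays of dendritic cells pretreated with sulforaphane and 2 arrays of cells given DMSO, all stimulated with LPS for 1 h. The series title names interleukin 23 and interleukin 12 in dendritic cells as its subject, and the comparison asks which transcripts differ in LPS-stimulated cells after sulforaphane. The medians of the arrays lay between 3.24 and 3.27 on the log2 scale. DMSO replicate 1 stood apart, with an interquartile range of 3.41 against 3.61 in DMSO replicate 2, 3.61 in sulforaphane replicate 1 and 3.62 in sulforaphane replicate 2. Over the 14652 genes tested, the SD of the log2 difference was 0.261 between the DMSO arrays and 0.209 between the sulforaphane arrays. Between arrays of different groups it ran from 0.266 to 0.317. DMSO replicate 2 lay about as far from sulforaphane replicate 1 (0.266) as from DMSO replicate 1 (0.261), so the DMSO arrays did not clearly group together.

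Sulforaphane-treated cells had more mRNA of Ednrb, the endothelin B receptor, and of Slc40a1, the iron exporter ferroportin, and less of F3, the coagulation initiator tissue factor. Ednrb rose 3.83-fold (log2 difference 1.94 ± 0.11 SE, n = 2 per group) and Slc40a1 3.47-fold (1.79 ± 0.11), while F3 was 4.74-fold lower (-2.25 ± 0.13), each with an adjusted p of 0.0136 by limma. Among the genes that fell, Tnfsf15, a TNF superfamily ligand, was 3.08-fold lower (-1.62 ± 0.11), Ltb, lymphotoxin beta, 3.03-fold lower (-1.60 ± 0.11), and Il12b, the subunit shared by IL-12 and IL-23, 2.49-fold lower (-1.32 ± 0.11). The other genes that fell were Ch25h, the cholesterol 25-hydroxylase (-1.55), Usp18, which removes ISG15 from proteins (-1.48), the orphan nuclear receptor Nr4a1 (-1.47), the interferon-inducible Ifi205 (-1.44), Rtp4 (-1.25) and the MAP kinase phosphatase Dusp2 (-1.17). A dimmer probe set of Ch25h differed by -0.58, and the mean of its probe sets by -1.07. The other genes that rose were Osgin1, an oxidative stress-responsive growth inhibitor (1.57), Proz, which encodes the plasma protein Z (1.55), the membrane channel Panx1 (1.45), Gdap10 (1.35), Frat1 (1.31), Eid3 (1.23) and the ubiquitin ligase adaptor Klhl21 (1.14).

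These were all 19 genes past the threshold, 9 higher and 10 lower, and in each the arrays of the 2 groups did not overlap. An unadjusted p under 0.05 was reached by 1899 of the 14652 genes, where chance alone gives a share of 0.05, so not all of these are differences. At least 1.5-fold without overlap, 194 genes were higher and 218 lower, 412 in all. No chance level was worked out for that count. The same rule marked 800 of 8210 probe sets with no symbol listed, of which limma called 0, so it also passes probe sets without a call. Of all genes tested, 43.6% had groups that did not overlap, against 33.3% by chance. That chance share is larger with an array left out, so the totals below without an array are not comparable with the 412. The split between higher and lower genes depended on scaling: median centring gave 41 higher and 102 lower past the threshold and 142 higher and 283 lower at 1.5-fold, and a second quantile normalization gave 34 higher and 72 lower past the threshold. It also turned with single arrays: at 1.5-fold, 482 genes were higher and 316 lower without DMSO replicate 2 (798 in all), 304 and 260 without sulforaphane replicate 1, 201 and 319 without DMSO replicate 1, and 245 and 275 without sulforaphane replicate 2. An exact permutation test of 2 against 2 arrays cannot give a two-sided p below 0.333, and no gene passed the limma threshold with any of the 4 arrays left out, when between 1036 and 2850 genes had an unadjusted p under 0.05.

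**Figure D1:**
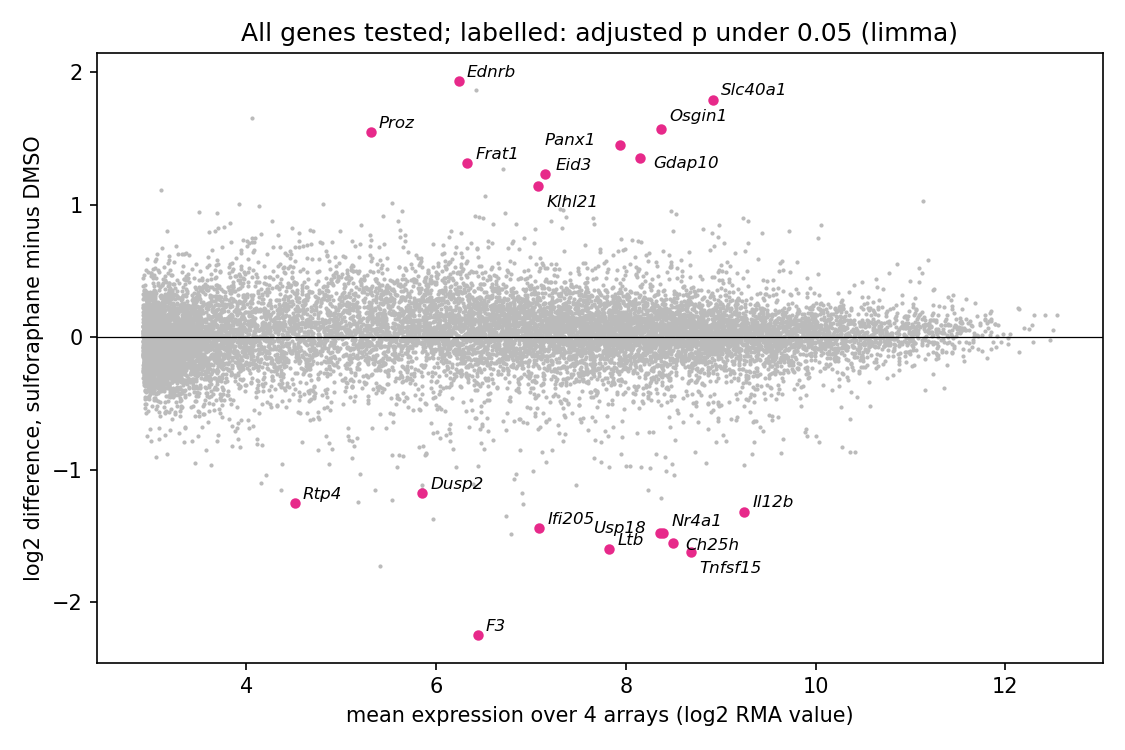
Each point is 1 of the 14652 genes tested, with its mean log2 expression over the 4 arrays on the x axis and the log2 difference between sulforaphane and DMSO on the y axis. The 19 labelled genes passed the adjusted threshold, from F3 at -2.25 to Ednrb at 1.94.

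Within the IL-12 family, transcripts of the subunits of IL-12 and IL-23 were lower after sulforaphane. Il12b fell from 9.90 ± 0.063 (SD, n = 2) to 8.59 ± 0.061 on the log2 scale (adjusted p = 0.0326 by limma over all genes). Il23a, the subunit specific to IL-23, went from 7.49 ± 0.24 to 6.32 ± 0.049, a difference of -1.17 ± 0.14 SE (95% interval -1.52 to -0.82), and Il12a, the other subunit of IL-12, from 4.08 ± 0.037 to 3.29 ± 0.17, a difference of -0.78 ± 0.13 (-1.09 to -0.47). Their adjusted p over all genes was 0.0565 and 0.0876, above the threshold, so 1 of the 5 members fell over all genes, and 3 of 5 fell when adjusted over the list alone. Il27 differed by -0.37 (-0.77 to 0.037) and Ebi3, which pairs with Il27, by -0.094 (-0.41 to 0.23), and neither passed either test. Without DMSO replicate 1 these were -0.15 and -0.23, and without DMSO replicate 2 -0.58 and 0.044. The list as a whole was lower (median -0.78, camera adjusted p = 6.0e-06; adjusted p = 0.316 with an estimated correlation; fry adjusted p = 0.045). The median of these 5 genes is the value of Il12a itself, whose sulforaphane mean of 3.29 lay near the median of all probe sets on those arrays (3.24), so the size of that difference is uncertain. In these arrays macrophage and mast cell markers had medians of -0.11 and -0.069 (camera adjusted p = 0.0120 and 0.0198; adjusted p = 0.388 and 0.497 with an estimated correlation; neither passed fry). Dendritic cell markers had a median of -0.069 (camera adjusted p = 0.0273; adjusted p = 0.413 with an estimated correlation), with 7 members above 0 and 8 below, that turned to 0.036 with the mean of probe sets and 0.045 with every probe set tested. The list was taken from the subject named in the series title, so its direction is not independent evidence. Il12b had no call with any single array left out, with differences between -1.36 and -1.27.

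**Figure D2:**
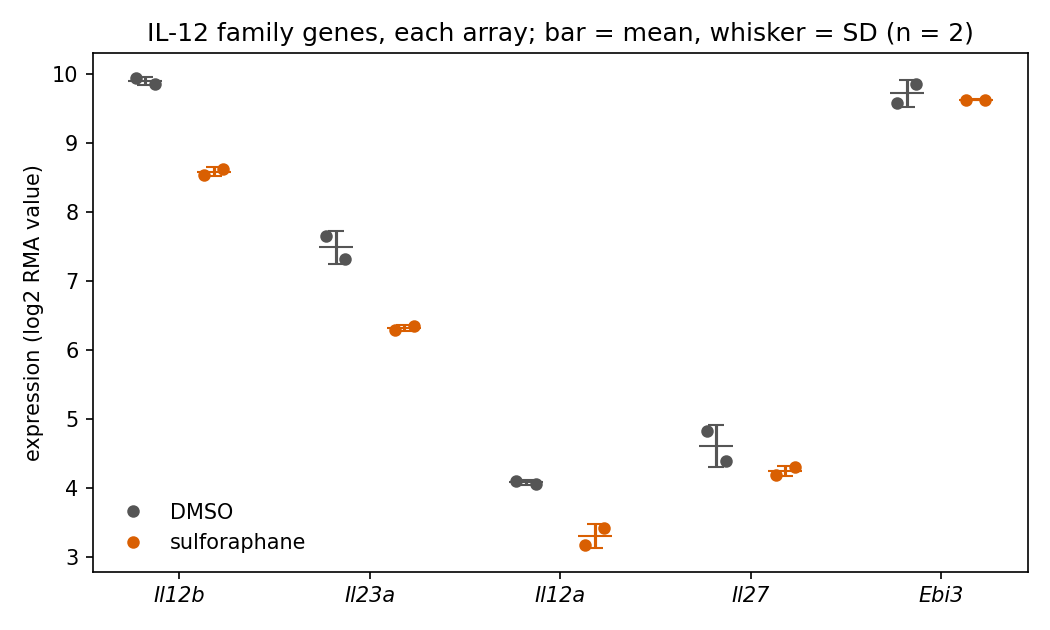
Log2 expression of the 5 IL-12 family genes on each array, with points for arrays, bars for group means and whiskers for the SD (n = 2). The DMSO and sulforaphane arrays of Il12b are centred at 9.90 and 8.59, and those of Ebi3 at 9.72 and 9.63.

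NRF2 targets, genes of glutathione synthesis, redox defence and detoxification, were higher as a group. Of 35 tested members 31 lay above 0, with a median of 0.42, and 21 rose and 0 fell when adjusted over the list alone. Over all genes, Osgin1 alone rose. Hmox1, the heme-degrading oxygenase, differed by 1.03 ± 0.11 SE, the carbonyl reductase Cbr3 by 1.87 ± 0.25 and the quinone reductase Nqo1 by 0.90 ± 0.12. These 3 passed over the list alone, with an adjusted p over all genes of 0.0510, 0.0592 and 0.0597. The list passed camera (adjusted p = 2.6e-15; adjusted p = 0.305 with an estimated correlation) and fry (0.0319). The medians of macrophage, mast cell and dendritic cell markers in the same arrays were -0.11, -0.069 and -0.069. These marker lists passed the same camera test as lower (adjusted p = 0.0120, 0.0198 and 0.0273). Like the NRF2 list, they did not pass camera with an estimated correlation (adjusted p = 0.388, 0.497 and 0.413), and none of them passed fry. The median of dendritic cell markers turned to 0.036 and 0.045 with the other choices of probe sets.

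Interferon-stimulated genes, the antiviral response downstream of type I interferon, were lower as a group. Of 33 tested members 29 lay below 0, with a median of -0.44. Over all genes Usp18 alone fell, and over the list alone 20 fell and 1 rose. Besides Usp18, those with the smallest p were the RNA-binding Ifit1 (-1.35 ± 0.15 SE), the mitochondrial kinase Cmpk2 (-1.07 ± 0.12) and the antiviral enzyme Rsad2 (-1.24 ± 0.14), all of which fell over the list alone. The member that rose over the list alone was the transcription factor Irf1 (0.47 ± 0.11), named after its value was seen. Camera gave an adjusted p of 8.0e-17, against an adjusted p of 0.316 with an estimated correlation and 0.0689 by fry, which did not pass. In the same arrays the median was -0.11 for macrophage and monocyte markers, -0.069 for mast cell markers and -0.069 for dendritic cell markers. These marker lists also passed camera as lower (adjusted p = 0.0120, 0.0198 and 0.0273). Like the interferon list, they passed neither camera with an estimated correlation (adjusted p = 0.388, 0.497 and 0.413) nor fry. The median of dendritic cell markers turned to 0.036 and 0.045 with the other choices of probe sets.

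NF-kB targets, cytokines and feedback genes that LPS induces were lower as groups. Of 32 NF-kB targets tested 26 lay below 0 (median -0.26), and 10 fell and 0 rose over the list alone, among them Bcl3 (-0.95 ± 0.11 SE), Nfkbie (-0.79 ± 0.11), Tnip1 (-0.71 ± 0.11) and Traf1 (-0.64 ± 0.13). Of 22 LPS-induced cytokines 20 lay below 0 (median -0.27), and over the list alone 7 fell, including Tnfsf15, the vasoconstrictor Edn1 (-1.04 ± 0.12), the macrophage growth factor Csf1 (-1.04 ± 0.17) and the activin subunit Inhba (-0.88 ± 0.15), and 1 rose, Il1f9 (0.55), named after its value was seen. Of 22 genes of cytokine feedback 15 lay below 0 and 7 above (median -0.21), and 5 fell over the list alone, including Bcl3, Trib1 (-0.85), Irak3 (-0.47) and Nr1h3 (-0.44). Of 36 immediate early genes 24 lay below 0 and 12 above, with 20 lower and 8 higher without overlap (median -0.17, and -0.11 without sulforaphane replicate 1). Over the list alone 10 fell and 2 rose, the latter being Mafk (0.42) and Dusp4 (0.51), named after their values were seen. Nr4a1 and Dusp2 fell over all genes, and Myc (-1.01) and Egr3 (-1.15) over the list alone. Among abundant members, Tnf, at 12.03 in DMSO, differed by -0.0075 (95% interval -0.27 to 0.25) and Ccl3 by 0.0074 (-0.27 to 0.29), while Il1b, at 11.55, fell over the list alone (-0.38). The 3 were named after their values were seen, and the difference of Tnf and Ccl3 from the IL-12 family genes was not tested. By camera, the adjusted p was 2.2e-09 for NF-kB targets, 2.1e-07 for LPS-induced cytokines, 3.2e-05 for cytokine feedback and 6.6e-05 for immediate early genes. In that order, adjusted p was 0.305, 0.305, 0.305 and 0.497 with an estimated correlation, and fry gave 0.0319, 0.0319, 0.0043 and 0.0895. Macrophage, mast cell and dendritic cell markers had medians of -0.11, -0.069 and -0.069 in the same arrays. These marker lists passed camera as lower too (adjusted p = 0.0120, 0.0198 and 0.0273). They did not pass camera with an estimated correlation (adjusted p = 0.388, 0.497 and 0.413), nor fry. The median of dendritic cell markers turned to 0.036 and 0.045 with the other choices of probe sets.

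**Figure D3:**
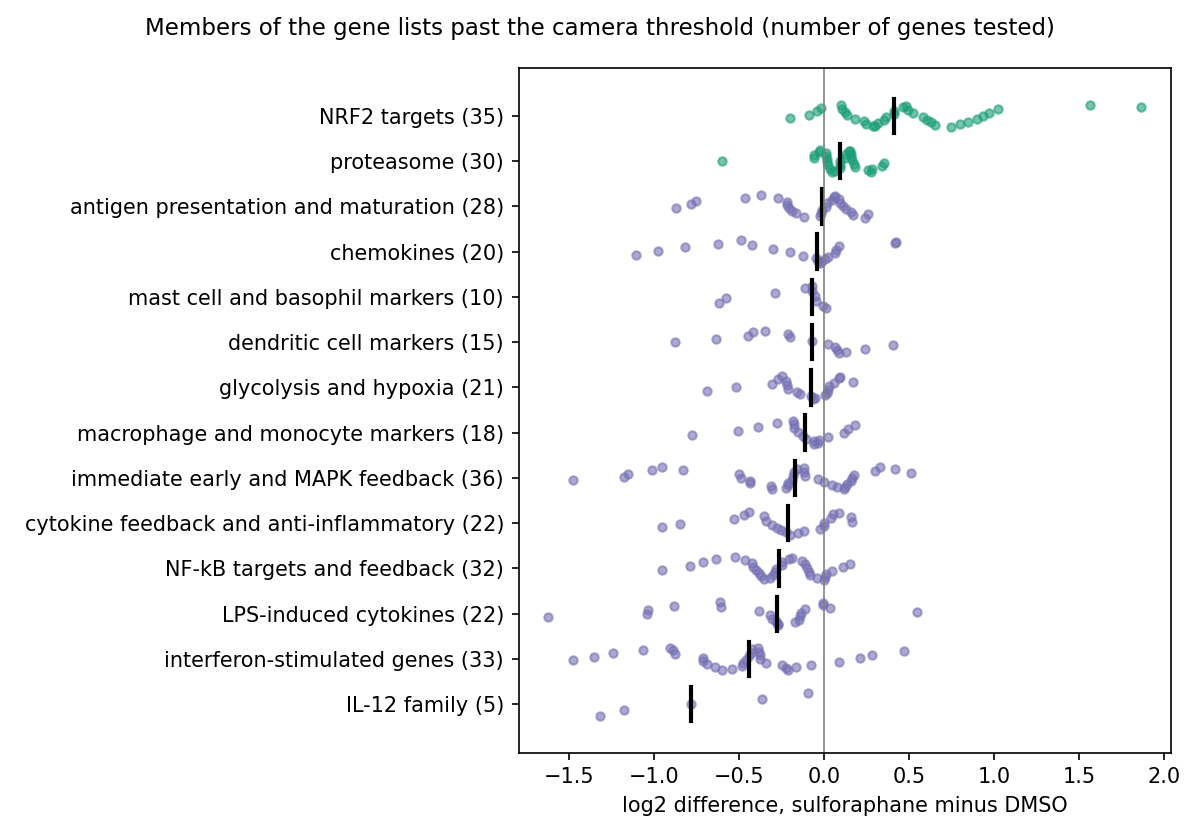
Each point is a tested member of 1 of the 14 lists past the camera threshold, with its log2 difference between sulforaphane and DMSO on the x axis, and the black bar is the list's median. Medians run from -0.78 for the IL-12 family to 0.42 for NRF2 targets.

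Single genes of antigen presentation, chemokines and cell type markers fell over their lists alone. Of 28 genes of antigen presentation and maturation 13 lay above 0 and 15 below, and 4 fell over the list alone, the costimulatory ligands Cd80 (-0.87 ± 0.11 SE) and Icosl (-0.78 ± 0.11), the receptor Cd40 (-0.75 ± 0.10) and the MHC class II activator Ciita (-0.46 ± 0.11), while the list's median was -0.012 and turned to 0.034 without DMSO replicate 2. Of 20 chemokines 13 lay below 0 and 5 fell over the list alone, Ccl4 (-0.98), Ccl7 (-1.11), Ccl2 (-0.62), Cxcl10 (-0.49) and Cxcl9 (-0.82, and -0.47 without DMSO replicate 2), and 1 rose, Cxcl2 (0.42), with a list median of -0.041 that ran from -0.15 without sulforaphane replicate 2 to -0.011 without sulforaphane replicate 1. Cxcl9 and Cxcl2 were named after their values were seen. Of 15 dendritic cell markers 7 lay above 0 and 8 below, and 3 fell over the list alone, the transcription factors Irf4 (-0.87) and Batf3 (-0.64) and the enzyme Kmo (-0.45), and the median of -0.069 turned to 0.036 with the mean of a gene's probe sets and 0.045 with every probe set tested. Of 18 macrophage and monocyte markers 14 lay below 0 and 1 fell over the list alone, the adhesion molecule Vcam1 (-0.78), while Mertk (-0.39), Ccr2 (-0.51, but -0.78 without DMSO replicate 1 and -0.23 without DMSO replicate 2) and Fcgr1 (-0.28, and -0.17 without sulforaphane replicate 1) did not pass (median -0.11). Of 10 mast cell and basophil markers 9 lay below 0 and 2 fell over the list alone, the histamine-forming enzyme Hdc (-0.61) and Gata2 (-0.57). Of 21 genes of glycolysis and hypoxia 13 lay below 0 and 2 fell over the list alone, Hk2 (-0.69) and Egln3 (-0.52). Of 30 proteasome genes 25 lay above 0 (median 0.097), led by Psmc1 (0.36) and Psmd4 (0.34), and 0 passed on their own.

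The camera adjusted p of these lists was 0.0318 for antigen presentation, 0.0198 for chemokines, 0.0273 for dendritic cell markers, 0.0120 for macrophage markers, 0.0198 for mast cell markers, 0.0198 for glycolysis and 0.0445 for the proteasome. In that order, adjusted p was 0.497, 0.413, 0.413, 0.388, 0.497, 0.550 and 0.624 with an estimated correlation, and none passed fry. Each of the 7 lost its call without sulforaphane replicate 1. Chemokines, mast cell markers and the proteasome lost it without DMSO replicate 1 too, and antigen presentation, dendritic cell markers, macrophage markers, glycolysis and the proteasome without DMSO replicate 2. The highest adjusted p with an array left out was 0.263 for antigen presentation, 0.134 for chemokines, 0.263 for dendritic cell markers, 0.0895 for macrophage markers, 0.144 for mast cell markers, 0.119 for glycolysis and 0.314 for the proteasome. Without DMSO replicate 1 the median was -0.17 for dendritic cell markers, -0.13 for macrophage markers, -0.12 for glycolysis and -0.053 for mast cell markers, and without sulforaphane replicate 2 it was -0.070, -0.065, -0.10 and -0.18 in that order. That of glycolysis was -0.038 without sulforaphane replicate 1, and that of the proteasome ran from 0.062 without DMSO replicate 1 or sulforaphane replicate 1 to 0.17 without DMSO replicate 2. The proteasome call was also lost with the filter at the 60th percentile, median centring and a second quantile normalization, that of chemokines with the filter at the 60th percentile, that of dendritic cell markers with the mean of probe sets and with every probe set tested, and that of glycolysis with every probe set tested. In all, 14 of the 32 lists passed camera, 12 lower and 2 higher, 0 with an estimated correlation and 5 by fry. The correlation alone does not account for that 0. For NF-kB targets it was estimated at -0.022, below the preset 0.01, and the unadjusted camera p still went from 2.0e-10 to 0.018. With so few degrees of freedom, a miss at an estimated correlation cannot decide about a list.

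The other 18 lists did not pass camera. Neutrophil and granulocyte markers had a median of 0.037 (-0.030 to 0.091 with an array left out) and a camera adjusted p of 0.967 with the opposite sign. Their members with the smallest p were Cebpe (-0.40) and Mpo (0.26). The adjusted p was 0.0829 for B cell markers, 0.169 for T and NK cell markers, 0.195 for plasmacytoid dendritic cell markers, 0.370 for erythroid and megakaryocyte markers and 0.643 for stromal markers. B cell markers passed without sulforaphane replicate 2 (median -0.31, adjusted p = 0.0030) and with every probe set tested (median -0.24), and plasmacytoid dendritic cell markers without DMSO replicate 1 (-0.44, 0.0370), but the median of B cell markers was 0.0084 without sulforaphane replicate 1 and that of plasmacytoid markers 0.0044 without DMSO replicate 2. With an array left out the adjusted p of B cell markers reached 0.571 and that of plasmacytoid markers 0.818. TLR4 signalling components had an adjusted p of 0.114, with Irak3 (-0.47) and Ikbkg (0.54) in opposite directions. For genes of ATF4 and the unfolded protein response it was 0.169, for inflammatory enzymes 0.195, for LXR targets 0.321, for cholesterol biosynthesis 0.321, for the cell cycle 0.421 and for p53 targets 0.536. For ribosomal proteins it was 0.562, for AhR targets 0.663, for the heat shock response 0.663, for oxidative phosphorylation 0.783 and for the metal response 0.967. The median lay below 0 and the mean above 0 for the heat shock response (-0.00051 and 0.056), oxidative phosphorylation (-0.0033 and 0.029) and the metal response (-0.013 and 0.11). Il10, Ifnb1 and Csf2 lay below the intensity filter and were not tested.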

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

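The probe sets with several gene symbols were left out of the comparison and were tested only after the main result was seen. They were fitted and adjusted as a set of their own, and so were those with no symbol listed. Their adjusted p-values are therefore not on the same footing as those of the main fit. Of 1118 such probe sets above the intensity filter, 2 passed the limma threshold, both higher after sulforaphane. Of the 1118, 109 had an unadjusted p under 0.05, where chance alone gives a share of 0.05. Probe set 17288112 differed by 1.33 ± 0.15 SE (4.07 in DMSO, 5.40 in sulforaphane) and probe set 17457232 by 1.17 ± 0.13 (5.06 and 6.23), each with an adjusted p of 0.0354. No gene is named from them, since each lists 2 symbols. Of 8210 probe sets with no symbol listed, also tested later, 0 passed the limma threshold. Their smallest limma adjusted p was 0.860, and 473 had an unadjusted p under 0.05, against a share of 0.05 by chance. Even so, 800 of them were at least 1.5-fold different without overlap, so that rule on its own does not mark a reliable change.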

How the results depend on the processing

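The threshold of 0.10 and its values were chosen after seeing the data; the other settings were planned. Of the 19 genes, 18 were still called without the intensity filter, 18 by robust eBayes, 19 with every probe set tested and 18 with the mean of probe sets. In the main fit the 20th to 35th ranked genes shared a limma adjusted p of 0.0510, so small changes could move many genes across the threshold. The number called depended strongly on the setting, and what moved it in each was not tested. It was 138 with the filter at the 60th percentile (57 higher, 81 lower; IL-12 family 2), 143 with median centring (41 higher, 102 lower; IL-12 family 3), 106 with a second quantile normalization (34 higher, 72 lower; IL-12 family 2), 34 with the mean of probe sets (11 higher, 23 lower), 249 with an intensity trend (96 higher, 153 lower; IL-12 family 2) and 173 at the 0.10 threshold (69 higher, 104 lower; IL-12 family 3). All 19 stayed among the genes called with the 60th percentile filter, median centring, the second quantile normalization and the trend. With any 1 array left out, leaving 1 residual degree of freedom and a lone array assumed to vary like the other group, limma called 0 genes (0 higher, 0 lower, 0 of the IL-12 family), with the smallest adjusted p between 0.0604 and 0.124; genes at least 1.5-fold without overlap then numbered 520 to 798, and lists past camera 7 to 15. Those 1.5-fold counts are not comparable with the 412 of all 4 arrays, since groups fail to overlap by chance more often with an array left out. The samples share only a replicate number: deviations of same-numbered arrays correlated at -0.081 over genes. With the replicate block 8 genes passed (4 higher, 4 lower), 0 of the IL-12 family, and 219 were at least 1.5-fold in the same direction within both pairs. Lists past the threshold fell from 14 to 0 with an estimated correlation and 5 by fry; camera has no robust option, so robust eBayes gave no list value. Among the 14 lists past camera, the median reversed for dendritic cell markers with the mean of probe sets (0.036) and every probe set (0.045), and for antigen presentation without DMSO replicate 2 (0.034; with each array left out -0.071 to 0.034). Of the other 18 lists, 13 had a median that changed sign in some setting, among them plasmacytoid dendritic cell markers (0.079 with the 60th percentile filter). The IL-12 family, NRF2, interferon, NF-kB, LPS-induced cytokine, cytokine feedback and immediate early lists passed camera with each array left out and in the other settings at the preset correlation. Calls were lost with the 60th percentile filter (chemokines, proteasome), median centring and a second quantile normalization (proteasome), the mean of probe sets (dendritic cell markers) and every probe set tested (dendritic cell markers, glycolysis). With the replicate block the calls of the proteasome, dendritic cell marker and antigen presentation lists were lost, and 11 lists passed. Signal near background limits the dim genes, such as Il12a at 3.29 after sulforaphane.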

Other observations

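Some lists that did not pass as a whole held single members that did over the list alone. Among genes of ATF4 and the unfolded protein response 2 rose and 1 fell, with Chac1, a glutathione-degrading enzyme, at 0.80 ± 0.11 SE, Atf4 at 0.47 ± 0.11 and the mTOR inhibitor Ddit4 at -0.94 ± 0.14. In the list of LXR targets and cholesterol efflux 1 rose, Mylip (0.66 ± 0.11), and 3 fell, Ch25h (-1.55), Nr1h3 (-0.44) and Abca1 (-0.47). Whether Ch25h, which stands in that list, acts as an LXR target in these cells was not tested. The metal response list held Slc40a1, which rose, and the zinc transporter Slc39a14 (-0.80 ± 0.13), which fell. Ptgs2, the inducible cyclooxygenase, fell by 0.90 ± 0.12 SE among the inflammatory enzymes, Car2 fell by 0.71 among erythroid markers, Bgn fell by 0.48 among stromal markers, Spib fell by 0.62 and Irf7 fell by 0.54 among plasmacytoid dendritic cell markers, and Trp53inp1 rose by 0.85 among p53 targets.

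The tests of neutrophil share, of bright probe sets and of gene name families, and the count of splits, were chosen only after the results were seen. The other tests had their bounds written before their values were seen, except that the bound for macrophage markers was reworded after its values were seen. It is used here as first written, and the reworded bound, that no bright member lie above 0, was not met by Lyz2 and would have left that test open.

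Interferon-stimulated genes were lower and NRF2 targets higher in the same arrays. A single array does not account for either: with each array left out the median closest to 0 was -0.38 for the interferon list and 0.37 for NRF2 targets. The narrower range of DMSO replicate 1 does not account for them either, with medians of -0.47 and 0.40 after a second quantile normalization. An effect of sulforaphane and an unrecorded difference in handling between the groups both stay open, as no test here separates them and replicate cultures are not documented.

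Macrophage and monocyte markers were lower by camera at the preset correlation (adjusted p = 0.0120). They did not pass camera with an estimated correlation (adjusted p = 0.388) or fry (adjusted p = 0.163). Their median ran from -0.13 to -0.065 with an array left out. A smaller share of these cells may contribute: 0 of the 11 bright members were higher without overlap, 5 were lower without overlap and 1 lay above 0, Lyz2 (0.14, but -0.13 without DMSO replicate 1). That bound was easily met, and the members were uneven, from Ccr2 at -0.51, which was -0.78 without DMSO replicate 1 and -0.23 without DMSO replicate 2, to Csf1r at -0.033 and Cd68 at -0.028, so regulation of single genes stays open. The rise of neutrophil markers written as the mark of a larger share of neutrophils was not seen. Their median was 0.037 (-0.030 to 0.091 with an array left out), with 1 member higher and 3 lower without overlap among 21. As 15 members lay above 0 and 6 below, and the bound was chosen after the results, a small rise in share is not excluded.

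Tnf and Ccl3 were close to 0 while Il12b and Il23a were lower. Compression of the brightest probe sets could hide a difference, and the tests left this open. Above a DMSO mean of 11, 0 of 245 genes differed by at least 1.5-fold without overlap, against 47 of 1987 between 9 and 11 (two-sided Fisher's exact p = 0.0076). With the bound 0.5 higher it was 0 of 76 (two-sided Fisher's exact p = 0.417), and both bounds were picked after a table of differences by brightness had been seen. Bright genes did differ by smaller amounts, since Icam1 (11.35 in DMSO, -0.40) and Il1b (11.55, -0.38) fell over their lists alone, and Hmox1, which its DMSO mean of 10.62 keeps out of the bright genes, reached 11.65 after sulforaphane, a difference of 1.03 (these 3 were named after their values were seen).

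Genes named Gpr, most of them G protein-coupled receptors, drew attention while the lower genes were read through, so the count that follows was made on the genes that prompted it. Of 38 tested, 7 were at least 1.5-fold lower without overlap, including Gpr18 (-1.15), Gpr183 (-0.98) and Gpr84 (-0.86), and 2 were higher, against 211 lower of 14614 other genes. Among 75 families of gene names with at least 20 tested genes, Gpr alone passed adjustment (two-sided Fisher's exact test, adjusted p = 9.4e-05). The 31 Gpr genes that had not prompted the idea had a mean of -0.045 against 0.029 for all genes not called lower, which did not pass (two-sided permutation p = 0.0573). A shift of the family may exist, but these data do not decide it.

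The 4 arrays can be split into pairs in 3 ways, too few for a share under 0.05. The real split gave 19 genes and the highest of the others gave 0, and the real split was the 1 split with as many.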
